A study of Mus musculus with 12 samples.

How the data were processed

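The study measured RNA in mouse CD4+ T cells by sequencing. There were 12 libraries in 4 groups of 3: Tfh_tumour, Tfh_WT, Tfh_OTII and Th1_WT, with each library assigned to its group from its title and source name. Per the labels, mice were C57BL/6J and 7 weeks old, RNA came from 300000 CD4+ T cells, libraries were stranded total RNA with ribosomal RNA removed, and reads were pairs of 75 bases quantified with kallisto on mm10. The kallisto version and the transcript annotation are not stated. The deposited values are TPM, transcript abundances corrected for length, with 1 value per gene symbol and 1 file per library. They were read as TPM because they are not whole numbers and each column sums to 1000000. The files analysed hold no counts, so the sequencing depth of each library is unknown, and no counting interval or detection floor can be given. A gene listed at 0 TPM is reported only as listed at 0.

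The files held 35492 symbols, of which 34699 (97.77%) matched GENCODE mouse release 21 and 714 were 0 in all 12 libraries. Positions of named genes are those of GRCm38 (mm10). Genes with a mean of at least 1 TPM in 1 group or more were tested (23308). limma 3.58.1 in R 4.3.3 was fitted to log2(TPM + 1) with 1 mean per group over all 12 libraries and an intensity trend in the prior variance. The 5 pairwise comparisons named in the report used contrasts of that fit, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in a comparison. Fold changes are differences of means of log2(TPM + 1), so they understate changes of genes near 0, and errors of fold changes are limma's moderated standard errors (SE). Tables were prepared and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Nothing in the labels says that the replicates of a group come from separate animals or cultures, so all p-values measure only the spread between these libraries, which may be technical. The design planned a count-based test and named limma on TPM as the choice for files without counts.

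Since TPM of a library sum to a constant, a few very abundant gene models lower all other values. Median-of-ratios size factors over 16404 genes were therefore computed as an alternative scaling. It moved the median log2 fold change of the tested genes by 0.742 in Tfh_WT against Th1_WT, 0.121 in Tfh_tumour against Tfh_WT, 0.055 in Tfh_OTII against Tfh_WT, 0.855 in Tfh_tumour against Th1_WT and 0.073 in Tfh_tumour against Tfh_OTII. In both comparisons with Th1_WT, counts of genes called are given as deposited and after scaling, camera p-values are those as deposited unless stated otherwise, and genes are said to have risen or fallen only when called in the same direction both ways.

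Before the data were examined, 32 gene lists, the named-gene rule, the tests and most alternatives were written down. The lists cover T helper programmes, cytokines, cytotoxicity, interferon responses, cell cycle, metabolism, stress, ribosomal and mitochondrial genes, and markers of other cell types. Each was tested with camera (limma), which asks whether a list moved more than the other genes, with a preset correlation between genes of 0.01, and p-values were adjusted over the lists of a comparison. With a correlation estimated from each list, the adjusted p of every list was above 0.05 in the 5 comparisons, and that value is given beside each call. Per list, the genes called over all genes tested are given with the number called when p-values were adjusted over the list alone. The position of a group between Tfh_WT and Th1_WT was the share of the genes called between those groups whose fitted difference from their midpoint had the Tfh_WT sign, with camera on the higher and lower genes, adjusted over the 4 tests of both groups. T cell receptor segment shares were compared by an exact permutation test.

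For the comparisons of Tfh_WT with Th1_WT, Tfh_tumour with Tfh_WT and Tfh_OTII with Tfh_WT, the rule named the 10 called genes with the highest and the 10 with the lowest fold change, at a mean of at least 5 TPM in the higher group and with no overlap between the groups. It named 5 and 5 for the other comparisons, up to 3 members higher and 3 lower per list, all members where a list had 5 or fewer called, and always Cxcr5, Bcl6, Pdcd1, Il21, Tbx21, Ifng, Foxp3, Cd4 and Cd8a. Gene models without a standard name, pseudogenes, small RNA and ribosomal RNA genes, mitochondrial genes and immunoglobulin or T cell receptor segments were not named by it. The text gives a part of the genes the rule named, so that each group is represented. The satellite-like models were singled out after their values were seen.

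The alternatives were median-of-ratios and trimmed-mean scaling, scaling on genes at 10 TPM or more, a pseudocount of 0.1, no filter, a filter at 5 TPM, named protein-coding genes alone, a fit of only the groups compared, the replicate number as a block, each library left out in turn, for positions, an estimated correlation, a fit of 3 groups and fewer axis genes, and, for lists, an estimated correlation and fry, a test of whether a list's genes move on balance in 1 direction. The method was tested on simulated data of the same size, with 50 changed genes per fold change and 5 simulations. Changed genes were drawn from those at a mean of about 5 TPM or more, and a gene had the same spread in every group. Recovery at lower TPM, and calls with unequal spread between groups, were thus not measured. For Tfh_tumour against Tfh_WT, 56% of genes changed 4-fold and 3.2% of genes changed 2-fold were called, with 0.02% of unchanged genes called. With a mean satellite share of Th1_WT added to each of its libraries, 21.87% of unchanged genes were called on values as deposited and 0.02% after scaling. camera called 20 of 20 simulated lists of 25 genes shifted 1.5-fold and 0 of 20 unchanged lists, with the preset and the estimated correlation alike. The simulated genes varied independently, whereas correlations estimated in the real lists ranged from 0.062 to 0.913, so the simulation does not bear on calls that depend on that correlation.

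Near-identical genes (Ifit3 and its neighbours, Gbp6, histone, ribosomal protein and Klra genes, Trav14 segments) share reads, so their split between copies is uncertain. Xist and Malat1 were not among the symbols. Time in culture could not be modelled, since it is confounded with group.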

Results

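RNA was sequenced from mouse CD4+ T cells in 12 libraries, 3 in each of 4 groups. Tfh_tumour libraries came from CD4+ CXCR5+ PD1+ cells, the surface phenotype of follicular helper T (Tfh) cells, sorted from MC38 tumours, which grow from a mouse colon carcinoma line. Tfh_WT libraries came from naive wild-type cells cultured with 50 ng/ml IL-6, 50 ng/ml IL-21 and antibodies that block IL-4, IFNγ and TGFβ. Tfh_OTII libraries came from the same culture started from OT-II mice, whose T cells carry a transgenic receptor for an ovalbumin peptide. Th1_WT libraries came from naive wild-type cells cultured with 10 ng/ml IL-12 and an antibody that blocks IL-4. Titles give 24 h of culture for Tfh_WT and Th1_WT and 48 h for Tfh_OTII, whereas the treatment protocol gives 48 h for both kinds of culture. The deposited TPM values carry no sequencing depth, so depth is unknown. Spearman correlations between libraries of a group, over genes, ranged from 0.940 to 0.954 in Tfh_WT, from 0.908 to 0.925 in Tfh_OTII, from 0.897 to 0.911 in Tfh_tumour and from 0.863 to 0.885 in Th1_WT.

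A small set of gene models took very different shares of the 4 groups' transcripts. The 12 models lie in repeat arrays on chromosome 9 (9 models between 3000922 and 3038316), chromosome 2 (2 models between 98662237 and 98667301) and chromosome 14 (1 model), and resemble satellite DNA, the tandem repeat of centromeric regions. They made up 46.5 ± 14.5% of TPM in Th1_WT (SD, n = 3), 12.4 ± 8.03% in Tfh_tumour, 8.16 ± 5.26% in Tfh_WT and 0.281 ± 0.186% in Tfh_OTII. The model Gm10800 alone (chr2, 98666547 to 98667301, minus strand) had 320000 ± 97000 TPM in Th1_WT and 51600 ± 32100 in Tfh_WT. Lars2, which encodes a mitochondrial leucyl-tRNA synthetase, took 14.5% of TPM in Th1_WT replicate 1 and 0.142% in replicate 2. Genes listed at 0 made up 32.2 ± 11.4% of all symbols in Th1_WT and 10.2% in Tfh_WT. Because TPM of a library add up to a fixed sum, all other genes of Th1_WT are lowered in values as deposited; the median-of-ratios size factor was 0.559 ± 0.105 in Th1_WT, against group means of 1.29 in Tfh_tumour, 1.17 in Tfh_WT and 1.22 in Tfh_OTII.

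**Figure D1:**
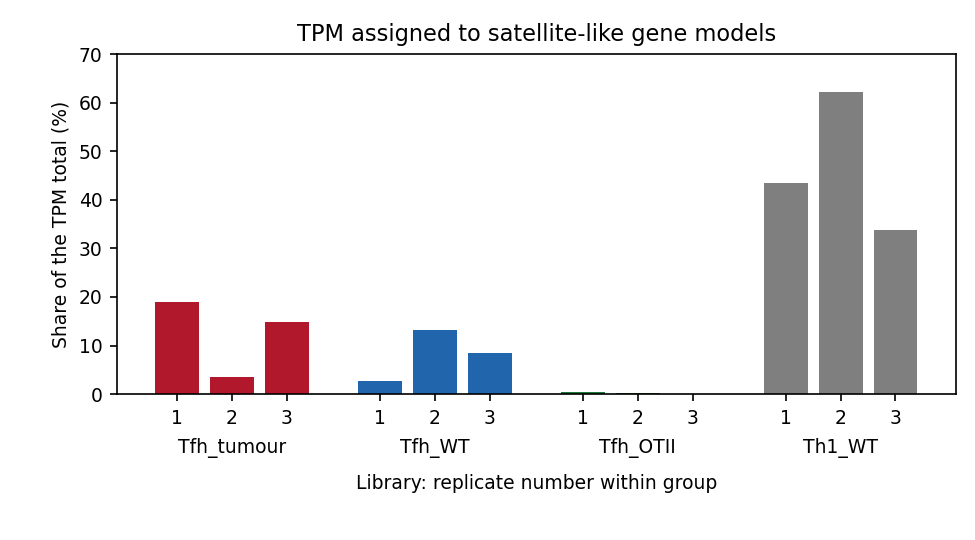
Share of TPM (percent, linear axis from 0) taken by the 12 satellite-like gene models, with 1 bar per library, grouped by sample group. Th1_WT libraries lie between 33.7% and 62.3%, Tfh_tumour between 3.48% and 19.0%, Tfh_WT between 2.75% and 13.3%, and Tfh_OTII between 0.0873% and 0.458%.

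T cell receptor segments were used to check the OT-II labels, since the OT-II receptor is built from segments of the Trav14 and Trbv12 families. Trav14 segments made up 86.0 ± 2.12% of alpha variable segment TPM in the 3 Tfh_OTII libraries and 11.4 ± 1.43% in the 9 others (SD; exact two-sided permutation p = 0.00909, the smallest that 220 arrangements gave). Trbv12 segments made up 35.4 ± 0.658% of beta variable segment TPM in Tfh_OTII and 4.73 ± 1.70% in the others (exact two-sided permutation p = 0.00909). The Y-linked genes Ddx3y (chrY, 1260771 to 1286629, minus strand), an RNA helicase, and Eif2s3y (chrY, 1010543 to 1028847, plus strand), a translation initiation factor, ranged from 29.7 to 37.6 and from 50.2 to 86.5 TPM in Tfh_OTII. Neither exceeded 2.24 TPM in the 9 other libraries. The Y-linked gene Kdm5d ranged from 22.6 to 39.1 TPM in Tfh_OTII. It reached at most 22.1 TPM in the 9 other libraries, so the ranges did not overlap but nearly met. The Y-linked gene Uty did not separate Tfh_OTII in this direction, with up to 310 TPM outside Tfh_OTII and from 28.3 to 43.7 TPM within it. The sex of the mice is not stated.

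The comparison of Tfh_WT with Th1_WT addresses how the IL-6 and IL-21 culture differs from the IL-12 culture in wild-type cells. Il21, which encodes the main cytokine of follicular helper cells (chr3, 37222759 to 37232636, minus strand), rose from 5.02 ± 3.19 TPM in Th1_WT to 88.5 ± 11.9 TPM in Tfh_WT (SD, n = 3 each). Its log2 fold change was 4.07 ± 0.38 as deposited (SE; adjusted p = 1.22e-05) and 3.16 ± 0.42 after scaling (adjusted p = 0.000542). Foxp3, which encodes the defining transcription factor of regulatory T cells (chrX, 7573644 to 7595245, plus strand), rose from 0.9 ± 0.544 to 24.4 ± 10.1 TPM, by 3.68 ± 0.39 log2 as deposited and 3.05 ± 0.34 after scaling. The inhibitory receptors Ctla4 and Tigit rose to 181 ± 23.8 and 263 ± 77.4 TPM, by 2.33 and 2.35 log2 after scaling. The folate receptor family member Izumo1r and the ectonucleotidase Nt5e (CD73), both high on regulatory and anergic cells, rose by 1.65 and 2.12 log2 after scaling. The nuclear receptor gene Rora rose by 1.40 log2 after scaling. Il17a rose by 2.05 ± 0.47 log2 after scaling, a call that was lost without Tfh_WT replicate 1 on the scaled values. Of naive-state genes, which went both ways as a list, Lef1, a partner of TCF1, and S1pr1, a receptor for exit from lymph nodes, rose by 1.34 and 1.84 log2 after scaling. Igfbp4, another naive-cell gene, rose from 18.6 ± 2.59 to 437 ± 86.6 TPM.

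Birc5, which encodes the mitotic protein survivin (chr11, 117849251 to 117855743, plus strand), rose from 3.78 ± 1.12 TPM in Th1_WT to 68.3 ± 9.89 TPM in Tfh_WT, by 3.87 ± 0.24 log2 as deposited (adjusted p = 5.91e-07) and 2.95 ± 0.25 after scaling (adjusted p = 2.34e-05). The anaphase ubiquitin enzyme Ube2c and cyclin B1 (Ccnb1) rose by 2.78 and 2.35 log2 after scaling. Among targets of hypoxia-inducible factors, the mitophagy receptor Bnip3l rose from 19.9 ± 8.89 to 334 ± 55 TPM, the prolyl hydroxylase Egln3 by 3.43 log2 after scaling and the glucose transporter Slc2a3 by 2.15. The glycolytic enzyme Aldoc rose by 2.59 log2 after scaling. Of secreted products, the chemokine Ccl1 rose from 0.765 ± 0.907 to 42 ± 13 TPM and the opioid peptide precursor Penk from 2.53 ± 1.56 to 32.7 ± 14.1 TPM. Genes lower in Tfh_WT included the lipase Lipe, which fell from 84.6 ± 46 to 9.96 ± 0.882 TPM (log2 fold change -2.76 ± 0.41 as deposited, -3.80 ± 0.34 after scaling), and the chromatin remodeller Smarcad1, which fell from 895 ± 283 to 149 ± 27.5 TPM. Ccdc162, a coiled-coil gene, had a log2 fold change of -4.85 after scaling, the epithelial anchoring gene Lad1 of -2.81 and the interferon-induced tetherin gene Bst2 of -2.53. The surface antigen Thy1 rose by 1.67 log2 after scaling.

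Cxcr5, Bcl6, Pdcd1, Cd8a, Tbx21, Ifng and Cd4 were called either only as deposited, only after scaling or not at all. Cxcr5, the follicular homing receptor, had 6.52 ± 0.938 TPM in Tfh_WT and 1.83 ± 0.829 in Th1_WT (SD, n = 3 each). It was called as deposited (log2 fold change 1.45 ± 0.29, adjusted p = 0.00172) and not after scaling (0.68 ± 0.30, adjusted p = 0.151; range over alternatives 0.00115 to 0.22). Bcl6, the main follicular transcription factor, had the same outcome (1.39 ± 0.23 as deposited and 0.61 ± 0.21 after scaling, adjusted p = 0.0761; range over alternatives 0.000449 to 0.143). Pdcd1, which encodes PD1, was called as deposited (1.27 ± 0.37, adjusted p = 0.0157) and not after scaling (0.30 ± 0.35, adjusted p = 0.6; range over alternatives 0.000671 to 0.641). The Pdcd1 call was also lost without Tfh_WT replicate 3 (adjusted p = 0.0606) and without Th1_WT replicate 1 (0.0563). Cd8a was called as deposited (1.34 ± 0.29) and not after scaling (0.54 ± 0.27, adjusted p = 0.197; range over alternatives 0.00245 to 0.234). Tbx21, which encodes the Th1 regulator T-bet, was not called as deposited (-0.39 ± 0.35, adjusted p = 0.357) and was lower in Tfh_WT after scaling (-1.40 ± 0.30, adjusted p = 0.00816; range over alternatives 0.00314 to 0.994). Ifng, the main Th1 cytokine, had 94.4 ± 27.9 TPM in Tfh_WT and 135 ± 72 in Th1_WT and was not called either way (adjusted p = 0.542 as deposited and 0.0915 after scaling; range over alternatives 0.0735 to 0.995). Cd4 was not called (0.63 as deposited, adjusted p = 0.213, and -0.43 after scaling, adjusted p = 0.429; range over alternatives 0.000232 to 0.631), but without Th1_WT replicate 3 its log2 fold change was 1.26 (adjusted p = 0.000232).

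The 3 highest fold changes that the rule named were those of Ttyh1, Tmem38b and Ctrc. The chloride channel gene Ttyh1 (chr7, 4119408 to 4136708, plus strand) had 4630 ± 770 TPM in Tfh_WT and 2.63 ± 1.3 in Th1_WT. Tmem38b, an intracellular cation channel gene (chr4, 53826045 to 53862019, plus strand), had 15500 ± 3130 and 22.7 ± 20.3 TPM. The digestive protease gene Ctrc (chr4, 141814962 to 141846359, minus strand) had 9190 ± 539 and 13.2 ± 3.58 TPM. The zinc finger gene Zfp101, the transcription export gene Eny2, the ubiquitin ligase gene Rnf225 and the histone genes Hist1h2af and Hist1h2ag rose by 5.72, 5.51, 4.86, 5.15 and 4.04 log2 after scaling. Exons of Tmem38b, Eny2 and Rnf225 overlap small RNA genes on the same strand.

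Of 23308 genes tested, limma called 9569 higher and 119 lower in Tfh_WT as deposited (98.8% higher), 9688 in all, and 6336 without Tfh_WT replicate 3. After scaling, 2104 were higher and 1248 lower (62.8% higher), 3352 in all, and 1521 and 1647 without Tfh_WT replicates 2 and 3. The genes called both ways numbered 2104 higher and 118 lower. Of 40 cell cycle genes, 39 were higher as deposited and 27 after scaling, 40 when adjusted over the list alone (camera adjusted p = 8.6e-20, adjusted p = 0.518 with an estimated correlation). Of 21 Treg programme genes, 18 were higher, 0 lower and 3 not called, 19 higher when adjusted over the list alone (camera adjusted p = 2.11e-06, adjusted p = 0.518 with an estimated correlation); after scaling 12 were higher, and 7 without Tfh_WT replicate 3. Of 21 hypoxia response genes, 18 were higher and 3 not called, 19 higher when adjusted over the list alone, and 11 were higher after scaling (camera adjusted p = 1.23e-06, adjusted p = 0.518 with an estimated correlation). Of 21 glycolysis genes, 19 were higher as deposited, 20 when adjusted over the list alone, and 3 were higher and 1 lower after scaling, 5 higher without Th1_WT replicate 3 (camera adjusted p = 0.00248, adjusted p = 0.747 with an estimated correlation). The glycolysis call was lost with trimmed-mean scaling (adjusted p = 0.0504) and the filter at 5 TPM (0.0904; range over alternatives with the preset correlation 2.84e-05 to 0.0904).

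Where 6 counts follow a count, they are those without Tfh_WT replicates 1, 2 and 3 and then without Th1_WT replicates 1, 2 and 3. Of 27 Tfh programme genes, 20 were higher and 7 not called as deposited, and 20 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00306, adjusted p = 0.518 with an estimated correlation). The call was lost with trimmed-mean scaling (adjusted p = 0.0504) and the filter at 5 TPM (0.123; range over alternatives with the preset correlation 8.87e-05 to 0.123). After scaling 9 of them were higher (5, 6, 4, 7, 8 and 8) and 3 lower (2, 1, 1, 3, 3 and 2). Of 24 genes of the IL-6 and IL-21 STAT3 response, 19 were higher and 5 not called, and 20 were higher when adjusted over the list alone (camera adjusted p = 0.00273, adjusted p = 0.723 with an estimated correlation). That call was lost with the filter at 5 TPM (adjusted p = 0.124; range over alternatives with the preset correlation 7.91e-05 to 0.124). After scaling 11 were higher (6, 7, 5, 7, 9 and 11) and 2 lower (2, 1, 0, 2, 3 and 2). Of 14 Th17 programme genes, 12 were higher and 2 not called, 14 were higher when adjusted over the list alone, and 4 after scaling (2, 3, 3, 4, 6 and 4). The Th17 camera call (adjusted p = 0.0108, adjusted p = 0.518 with an estimated correlation) was lost without Th1_WT replicate 3 (adjusted p = 0.0738) and with the filter at 5 TPM (0.187; range over alternatives with the preset correlation 0.000349 to 0.187). Of 23 Th1 programme genes, 13 were higher in Tfh_WT as deposited, also when adjusted over the list alone (camera adjusted p = 0.403). After scaling 4 were higher (0, 1, 0, 1, 3 and 2) and 1 lower (1, 1, 1, 4, 1 and 2). Of 17 naive and central memory genes, 10 were higher and 1 lower as deposited, and 11 and 1 when adjusted over the list alone. After scaling 6 were higher (3, 3, 4, 5, 4 and 6) and 2 lower (2, 2, 2, 3, 4 and 2), with a median of 0.06. Camera did not call the list (adjusted p = 0.233 as deposited and 0.768 after scaling).

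Of interferon gamma response genes, as deposited 7 of 31 were higher in Tfh_WT (12 without Th1_WT replicate 3) and 6 when adjusted over the list alone. After scaling 8 were lower, 5 without Tfh_WT replicate 1 or Th1_WT replicate 2 and 3 without Tfh_WT replicate 2 or 3, and 14 when adjusted over the list alone. Their median log2 fold change was 0.20 as deposited, below the 0.778 of all tested genes, so that camera, which compares with other genes, gave a downward call (adjusted p = 0.00306, adjusted p = 0.852 with an estimated correlation). That call was lost without Tfh_WT replicate 2 (adjusted p = 0.0509) and without Th1_WT replicate 3 (0.353). Camera also called the dendritic cell and antigen presentation markers (adjusted p = 0.000201, 0.00408 after scaling, adjusted p = 0.518 with an estimated correlation) downward. The B cell markers were called downward too (camera adjusted p = 4.15e-05, 0.000131 after scaling, adjusted p = 0.518 with an estimated correlation). Of 16 dendritic cell markers, 1 was higher as deposited (2, 0, 0, 0, 0 and 1 without Tfh_WT and then Th1_WT replicates 1 to 3) and 0 when adjusted over the list alone, and 4 were lower after scaling (2, 1, 1, 5, 2 and 2 in the same order). Their medians were 0.23 and -0.59. Of 16 B cell markers, 1 was higher (2 without Th1_WT replicate 1) and 1 lower as deposited (1, 0, 0, 1, 0 and 0), 1 higher when adjusted over the list alone, and 5 were lower after scaling (2, 3, 2, 7, 5 and 4). These had medians of -0.04 and -0.78 and means of 0.15 and -0.65. The ribosomal protein gene Rpl5 rose from 81.9 ± 23 to 1790 ± 55.1 TPM. Of all 30 ribosomal protein genes, 9 were higher as deposited (5, 6, 7, 6, 6 and 23), also when adjusted over the list alone. After scaling Rpl5 was higher and 4 were lower (4, 0, 0, 3, 2 and 2). Their medians were 0.65 and -0.42. Camera did not call them as deposited (adjusted p = 0.639) but called them upward without Th1_WT replicate 3 (adjusted p = 0.017; range over alternatives with the preset correlation 0.00016 to 0.916). It called them downward after scaling (adjusted p = 0.000556, adjusted p = 0.83 with an estimated correlation). Of 18 unfolded protein response genes, 13 were higher as deposited and 14 when adjusted over the list alone (camera adjusted p = 0.128). After scaling 1 was higher and 3 were lower, with 0 lower without Tfh_WT replicate 2 or 3, 5 without Th1_WT replicate 1, and 0 higher without each library but Th1_WT replicate 3. Of 13 mitochondrially encoded genes, 10 were higher as deposited, 5 without each Tfh_WT library and 6 without Th1_WT replicate 3, and 11 when adjusted over the list alone (camera adjusted p = 0.0998). After scaling limma called 0 of them, 2 without Th1_WT replicate 2. Of 17 T cell identity genes, Thy1 among them, 9 were higher as deposited, 15 without Th1_WT replicate 3, and 10 when adjusted over the list alone (camera adjusted p = 0.0756). After scaling 3 were higher (1 without Tfh_WT replicate 1 or 2 or Th1_WT replicate 1) and 1 lower (2 without Th1_WT replicate 1, 0 without Tfh_WT replicate 2 or 3 or Th1_WT replicate 3).

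**Figure D2:**
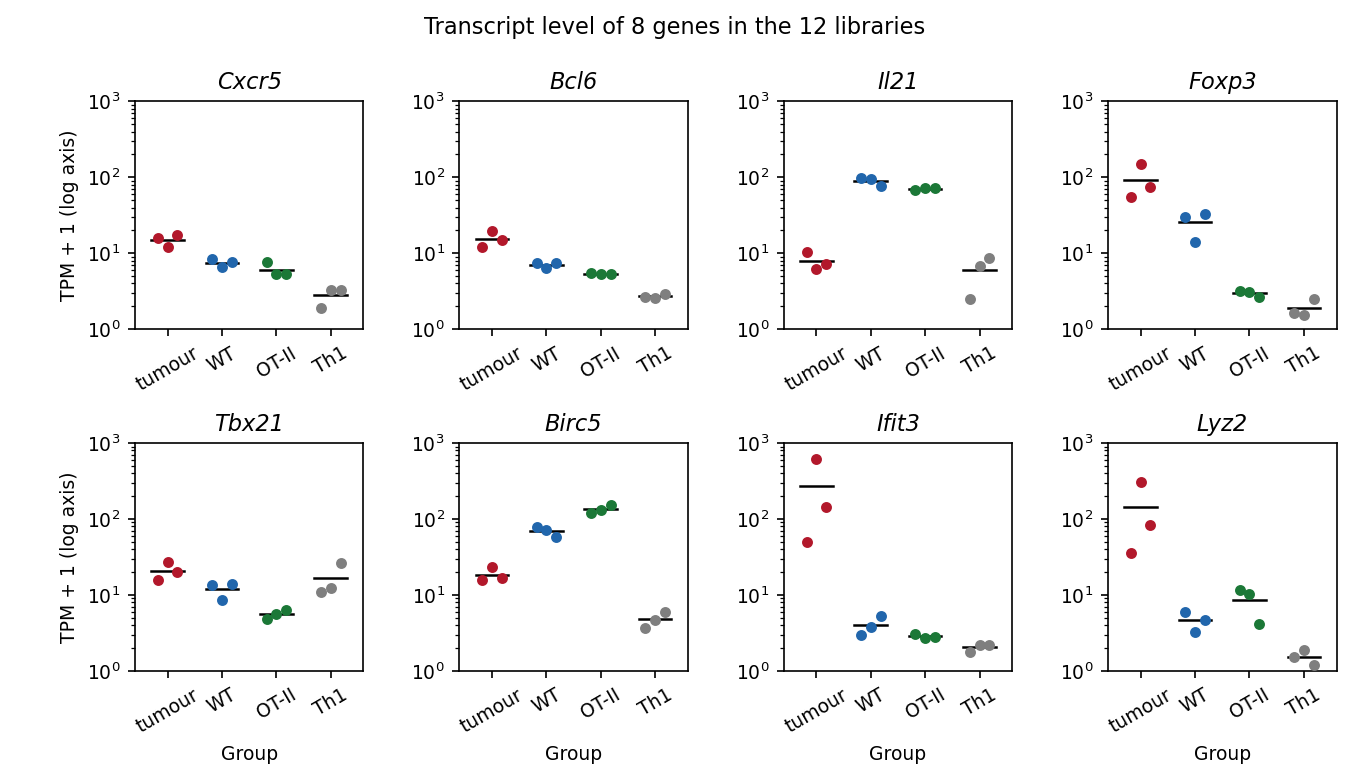
Transcript level (TPM + 1, log axis) of 8 genes, with 1 point per library and a bar at the group mean, in Tfh_tumour (tumour), Tfh_WT (WT), Tfh_OTII (OT-II) and Th1_WT (Th1). Il21 was between 66.8 and 97.8 TPM in the 6 libraries cultured with IL-6 and IL-21 and at most 9.25 TPM elsewhere, while Ifit3 and Lyz2 were highest in Tfh_tumour replicate 2.

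The comparison of Tfh_tumour with Tfh_WT asks how far Tfh cells from a tumour resemble the cultured cells of the same name; origin, sorting and culture differ together. Interferon-induced genes were among those with the highest fold changes. Ifit3, an antiviral gene (chr19, 34583531 to 34588731, plus strand), rose from 3.01 ± 1.22 TPM in Tfh_WT to 269 ± 303 in Tfh_tumour (SD, n = 3 each), by 5.40 ± 0.63 log2 (SE; adjusted p = 0.00184). Its relative Ifit1 rose by 3.88 ± 0.54 log2, the receptor transporter Rtp4 by 4.0 ± 0.53 and the DNA sensor family gene Ifi205 by 5.0 ± 0.64. The guanylate-binding protein Gbp6 rose from 24 ± 6.05 to 181 ± 102 TPM, and the immunity-related GTPase Irgm1 from 21 ± 5.09 to 119 ± 38.4 TPM. The interferon-induced chemokine Cxcl10 rose by 4.58 log2 (adjusted p = 0.00445) and the monocyte chemokine Ccl2 by 4.64 (adjusted p = 0.00562). Lyz2, the lysozyme of macrophages and neutrophils (chr10, 117277331 to 117282321, minus strand), rose from 3.6 ± 1.33 to 142 ± 147 TPM, by 4.44 ± 0.63 log2 (adjusted p = 0.00423). The macrophage itaconate enzyme Acod1 rose by 4.55 ± 0.62 log2, the lectin receptor Clec4n by 3.95 ± 0.49 and the neutrophil collagenase Mmp8 by 2.18 ± 0.33. Levels differed widely among the tumour libraries, with Lyz2 at 34.1, 309 and 82 TPM in replicates 1, 2 and 3.

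Genes lower in Tfh_tumour included Il21, Nrn1 and Slc2a3. Il21 was 6.89 ± 2.09 TPM in Tfh_tumour and 88.5 ± 11.9 in Tfh_WT, a log2 fold change of -3.53 ± 0.38 (adjusted p = 0.000938). Nrn1, a gene of anergic cells, had a log2 fold change of -2.17 ± 0.35, the naive-cell gene Igfbp4 of -1.74 ± 0.25 and the pseudokinase gene Trib2 of -2.33 ± 0.30. The division genes Birc5 and Tpx2, which act in mitosis, and Ccne1, the cyclin of S phase entry, had log2 fold changes of -1.92, -1.86 and -2.04. Slc2a3 fell from 75.8 ± 17.1 to 16.4 ± 2.13 TPM (-2.13 ± 0.21 log2, adjusted p = 0.000507), and the hypoxia-induced mitochondrial gene Fam162a had a log2 fold change of -1.81 ± 0.25. Bcl6 was 14.5 ± 3.97 TPM in Tfh_tumour and 6.09 ± 0.572 in Tfh_WT and was called (1.11 ± 0.23 log2, adjusted p = 0.0302; range over alternatives 0.0124 to 0.176). Without Tfh_tumour replicate 2 or 3 its adjusted p was 0.0997 or 0.1, and without Tfh_WT replicates 1, 2 or 3 it was 0.115, 0.176 or 0.0877. Foxp3 was 91.7 ± 48.6 against 24.4 ± 10.1 TPM and was called (1.84 ± 0.39 log2, adjusted p = 0.0307; range over alternatives 0.00669 to 0.168). Its adjusted p was 0.103 and 0.0811 without Tfh_tumour replicates 2 and 3, and 0.0871, 0.168 and 0.0534 without Tfh_WT replicates 1, 2 and 3. Cxcr5 (14 ± 2.72 against 6.52 ± 0.938 TPM, adjusted p = 0.102), Pdcd1 (31.4 ± 7.56 against 18.8 ± 2.71 TPM, adjusted p = 0.448), Tbx21 (adjusted p = 0.316), Ifng (adjusted p = 0.298), Cd4 (142 ± 27.6 against 149 ± 12.2 TPM, adjusted p = 0.968) and Cd8a (adjusted p = 0.873) were not called.

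In this comparison 269 genes were called higher and 220 lower by limma, 489 in all, and 434 of them (230 higher and 204 lower) were also called after scaling. Which direction held more genes depended on the processing, with 259 higher and 285 lower after scaling, 666 and 167 on named protein-coding genes alone, 129 and 272 in a fit of only these groups, and 150 and 194 without Tfh_tumour replicate 2. The count was 882 and 179 without Tfh_tumour replicates 1 and 3, and 105, 94 and 193 without Tfh_WT replicates 1, 2 and 3. Counts of list genes depended on single libraries too, and 6 counts after a list give those without Tfh_tumour replicates 1, 2 and 3 and then without Tfh_WT replicates 1, 2 and 3. Of 32 type I interferon response genes, 24 were higher and 8 not called (32, 17, 11, 8, 8 and 11), and 32 were higher when adjusted over the list alone. Their median log2 fold change was 2.52 (camera adjusted p = 5.75e-37, adjusted p = 0.209 with an estimated correlation). Of 31 interferon gamma response genes, 12 were higher (13, 8, 8, 5, 4 and 6) and 23 when adjusted over the list alone (camera adjusted p = 1.67e-19, adjusted p = 0.209 with an estimated correlation). Of 25 macrophage and monocyte markers, 11 were higher (18, 8, 4, 2, 2 and 3) and 22 when adjusted over the list alone, with a median of 2.25 (camera adjusted p = 5.19e-21, adjusted p = 0.209 with an estimated correlation). Of 12 neutrophil markers, 2 were higher (5, 2, 1, 1, 1 and 1), also when adjusted over the list alone (camera adjusted p = 0.00077, adjusted p = 0.497 with an estimated correlation). Of 16 dendritic cell and antigen presentation markers, 4 were higher (4, 3, 1, 0, 0 and 0) and 6 when adjusted over the list alone (camera adjusted p = 5.84e-08, adjusted p = 0.209 with an estimated correlation). Of 40 cell cycle genes, 16 were lower (10, 13, 6, 4, 4 and 7) and 28 when adjusted over the list alone, with a median of -1.14 (camera adjusted p = 2.73e-31, adjusted p = 0.209 with an estimated correlation). Of 21 hypoxia response genes, 6 were lower (3, 7, 2, 2, 2 and 2) and 11 when adjusted over the list alone (camera adjusted p = 1.16e-12, adjusted p = 0.209 with an estimated correlation). Of 21 glycolysis genes, 3 were lower and 13 when adjusted over the list alone (camera adjusted p = 1.74e-13, adjusted p = 0.209 with an estimated correlation). Of 30 ribosomal protein genes, limma called 0 over all genes, 2 without Tfh_tumour replicate 1, while 22 were lower when adjusted over the list alone and 23 at an unadjusted p under 0.05 (median -0.84; camera adjusted p = 3.05e-19, adjusted p = 0.209 with an estimated correlation).

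For T cell state lists of the same comparison, 6 counts in brackets follow the same order of libraries left out. Of 27 Tfh programme genes, 5 were higher (5, 1, 0, 0, 0 and 0) and 2 lower (2, 2, 2, 1, 2 and 2), and 10 and 4 when adjusted over the list alone. Camera did not call that list (adjusted p = 0.426), whose median was 0.09 as deposited and -0.05 after scaling. Of 23 Th1 programme genes, 2 were higher, and 4 were higher and 1 lower when adjusted over the list alone. Camera called the Th1 list upward (adjusted p = 0.0272, adjusted p = 0.707 with an estimated correlation). That call was lost with the filter at 5 TPM, alone (adjusted p = 0.127) and with scaling (0.0887). Of 21 Treg programme genes, 3 were higher, with 8 higher without Tfh_tumour replicate 1, 2 without Tfh_WT replicate 3 and 0 without each of the other 4 libraries, and 10 were higher when adjusted over the list alone (camera adjusted p = 2.31e-06, adjusted p = 0.362 with an estimated correlation). Of 20 checkpoint and exhaustion genes, 3 were higher and 5 when adjusted over the list alone (camera adjusted p = 5.83e-05, adjusted p = 0.355 with an estimated correlation); without Tfh_tumour replicate 2 or 3 or Tfh_WT replicate 3 the count was 1, and without Tfh_WT replicate 1 or 2 it was 0. Of 17 naive and central memory genes, 4 were lower and 5 when adjusted over the list alone (camera adjusted p = 0.00607, adjusted p = 0.455 with an estimated correlation). That list was not called without Tfh_WT replicate 1 (adjusted p = 0.072), where 1 gene was lower, and 2 were lower without Tfh_WT replicate 2. Of 14 tissue residency genes, limma called 0, 5 without Tfh_tumour replicate 1, with 4 higher and 1 lower when adjusted over the list alone and 7 higher and 1 lower at an unadjusted p under 0.05. Its camera call (adjusted p = 0.00395, adjusted p = 0.455 with an estimated correlation) was lost without Tfh_tumour replicate 2 (adjusted p = 0.0889). Of 31 immediate early and dissociation stress genes, limma called 0, 9 without Tfh_tumour replicate 1, with 2 higher when adjusted over the list alone and 6 higher and 1 lower at an unadjusted p under 0.05. Its camera call (adjusted p = 0.0256, adjusted p = 0.847 with an estimated correlation) was lost without Tfh_tumour replicate 2 (0.696) and without Tfh_WT replicates 2 (0.104) and 3 (0.108). Of 16 B cell markers, 1 was higher (1, 1, 0, 0, 0 and 0) and 7 when adjusted over the list alone (camera adjusted p = 5e-06, adjusted p = 0.209 with an estimated correlation). The lists of epithelial, of fibroblast and endothelial, and of red cell markers were not called. Of 10 tumour epithelial markers limma called 0, also at an unadjusted p under 0.05 and when adjusted over the list alone (camera adjusted p = 0.775). Of 17 fibroblast and endothelial markers 1 was lower, 1 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.824); without Tfh_tumour replicate 1, 1 was higher and 1 lower, and without each of the other libraries 0 were called. Of 4 red cell markers limma called 0, also when adjusted over the list alone, and 1 was higher at an unadjusted p under 0.05 (camera adjusted p = 0.122).

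**Figure D3:**
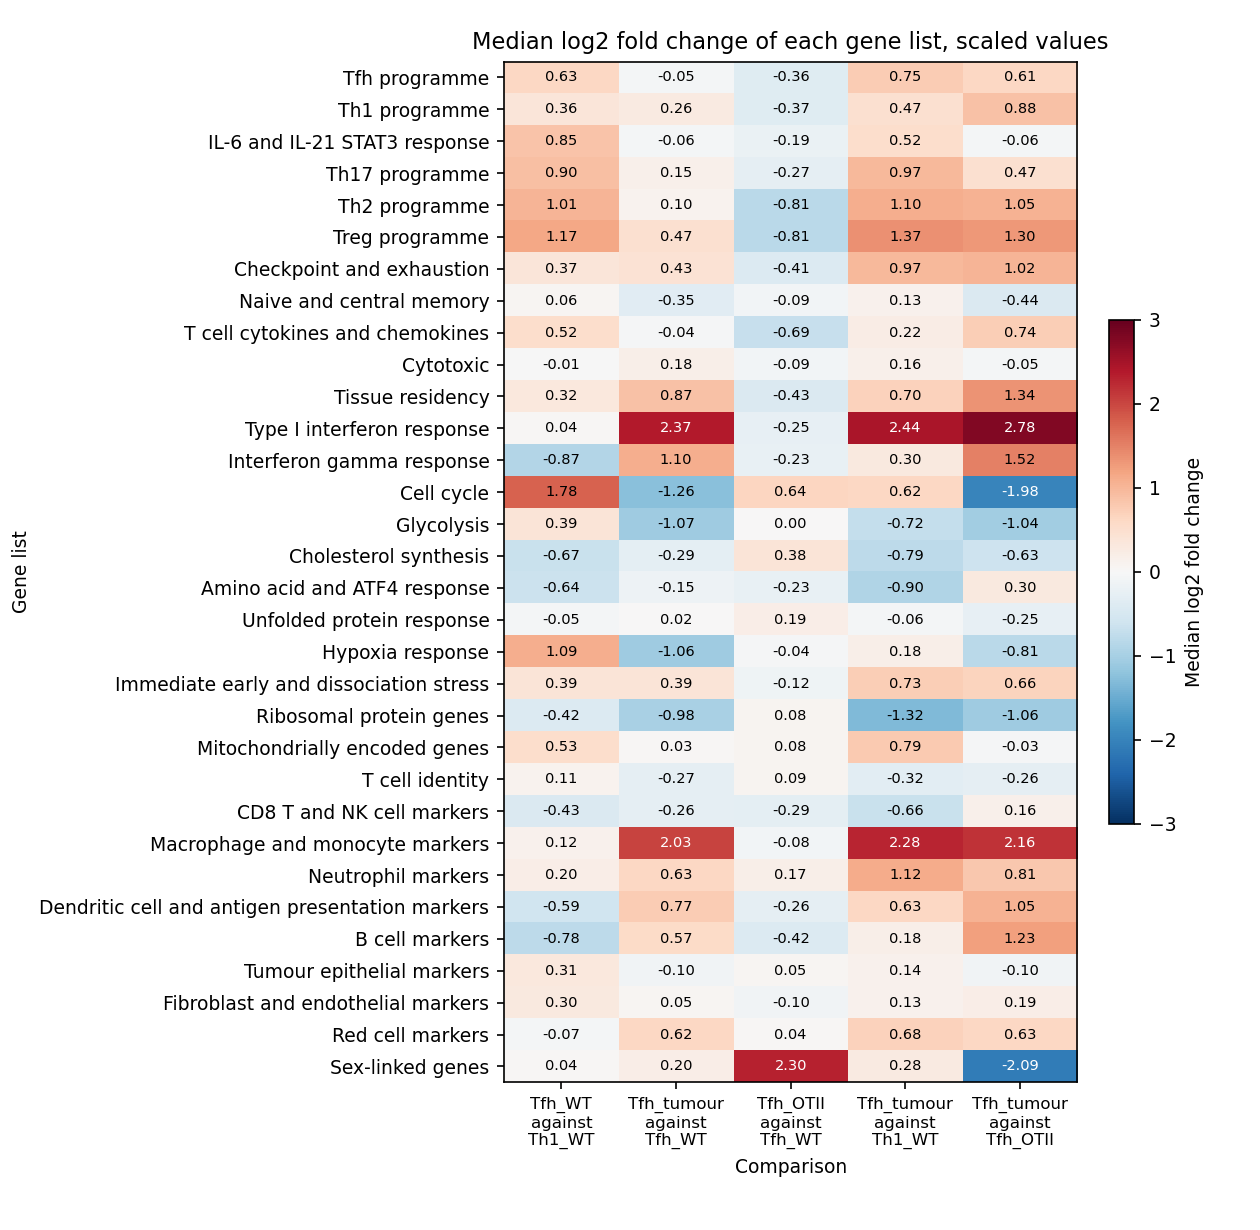
Median log2 fold change, after median-of-ratios scaling, of the genes of each of 32 lists (vertical axis) in the 5 comparisons (horizontal axis), as colour from blue (negative) to red (positive) with the value printed in each cell. The type I interferon response list has medians of 2.37, 2.44 and 2.78 in the 3 comparisons of Tfh_tumour, and the cell cycle list medians of -1.26 and -1.98 against Tfh_WT and Tfh_OTII and 0.62 against Th1_WT.

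The comparison of Tfh_OTII with Tfh_WT sets cells with the OT-II receptor against wild-type cells in the same cytokines, where receptor, hours in the title and Y-linked transcripts differ together. Foxp3 was 1.97 ± 0.273 TPM in Tfh_OTII and 24.4 ± 10.1 in Tfh_WT (SD, n = 3 each), a log2 fold change of -3.01 ± 0.39 (SE; adjusted p = 0.00186). Nt5e had a log2 fold change of -2.33 ± 0.28 (adjusted p = 0.000977), and Ccl1 fell from 42 ± 13 to 0.742 ± 0.849 TPM (-4.69 ± 0.49, adjusted p = 0.000319). Il10, the cytokine of regulatory cells, had a log2 fold change of -3.0 ± 0.54 (adjusted p = 0.0122; range over alternatives 0.00106 to 0.084), lost without Tfh_WT replicate 3 (0.084) and Tfh_OTII replicate 3 (0.0656). Its regulator Maf had -2.28 ± 0.43 (adjusted p = 0.0156; range over alternatives 0.00122 to 0.104), lost without the same libraries (0.104 and 0.0823). Among the genes that fell most were Xkrx, a membrane protein gene, from 170 ± 43.3 to 8.65 ± 6.87 TPM, the bacterial lipoprotein receptor Tlr1 from 391 ± 155 to 37.6 ± 22 TPM, and the unconventional myosin gene Myo7a from 334 ± 134 to 14.1 ± 10.6 TPM. Igkc, the kappa light chain constant gene of B cells, fell from 27.6 ± 4.01 to 8.75 ± 1.5 TPM. The T cell receptor alpha constant gene Trac (chr14, 54220521 to 54224206, plus strand) rose from 317 ± 60.4 to 2010 ± 79.9 TPM, by 2.68 ± 0.32 log2 (adjusted p = 0.000956). The Wnt pathway ubiquitin ligase Rnf43 rose from 4 ± 0.781 to 60.2 ± 4.28 TPM, and the kinetochore gene Cenpf from 14.7 ± 1.3 to 69.6 ± 6.28 TPM. Ccnb1 rose by 1.34 ± 0.22 log2 (adjusted p = 0.00742; range over alternatives 0.00176 to 0.0636), a call lost without Tfh_WT replicate 3 (0.058) and on named protein-coding genes alone (0.0636). Eif2s3y and Ddx3y rose by 4.99 ± 0.32 and 4.06 ± 0.28 log2. The lineage genes Il21 (69.8 ± 2.66 against 88.5 ± 11.9 TPM, adjusted p = 0.823), Bcl6 (adjusted p = 0.557), Cxcr5 (adjusted p = 0.75), Pdcd1 (adjusted p = 0.736), Cd4 (150 ± 8.53 against 149 ± 12.2 TPM, adjusted p = 0.999) and Cd8a (adjusted p = 0.355) were not called. Tbx21 (-1.06 ± 0.35, adjusted p = 0.156; range over alternatives 0.0273 to 0.514) and Ifng (-1.02 ± 0.50, adjusted p = 0.42; range over alternatives 0.0263 to 0.852) were not called either.

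In all, 230 genes were higher and 325 lower in Tfh_OTII by limma, 555 together, and 183, 144 and 223 without Tfh_WT replicates 2 and 3 and Tfh_OTII replicate 3. The balance turned to 2215 higher and 642 lower in a fit of only these groups, and to 92 and 91, 77 and 67, and 130 and 93 without those libraries. It was 158 and 283 after scaling, 482 and 741 in the fit of only these groups with scaling, and 40 and 238 on named protein-coding genes alone. Of 4 sex-linked genes, 2 were higher and 1 lower, 3 and 1 when adjusted over the list alone (camera adjusted p = 0.000551, adjusted p = 0.163 with an estimated correlation); the lower gene was called without Tfh_WT replicate 1 and Tfh_OTII replicates 1 and 2 and not without the other 3 libraries. Of 32 T cell cytokines and chemokines, 2 were lower, 1 without Tfh_WT replicate 3 or Tfh_OTII replicate 3, and 7 when adjusted over the list alone (camera adjusted p = 3.99e-09, adjusted p = 0.163 with an estimated correlation). Of 11 Th2 programme genes, 1 was lower, 0 without Tfh_WT replicate 3 or Tfh_OTII replicate 3, and 3 when adjusted over the list alone (camera adjusted p = 3e-06, adjusted p = 0.163 with an estimated correlation). Treg programme genes were lower in 6 of 21 cases (2, 4, 1, 3, 4 and 1 without Tfh_WT replicates 1 to 3 and then Tfh_OTII replicates 1 to 3) and in 7 when adjusted over the list alone (camera adjusted p = 3.99e-09, adjusted p = 0.41 with an estimated correlation). Cell cycle genes were higher in 7 of 40 cases (4, 2, 1, 4, 4 and 2 in the same order) and in 16 when adjusted over the list alone (camera adjusted p = 2.18e-15, adjusted p = 0.41 with an estimated correlation). Of 24 cholesterol synthesis genes limma called 0, with 1 higher when adjusted over the list alone and 8 higher at an unadjusted p under 0.05 (camera adjusted p = 1.95e-05, adjusted p = 0.435 with an estimated correlation). Tfh programme genes were lower in 1 of 27 cases, 0 without Tfh_WT replicate 3 or Tfh_OTII replicate 3, and 1 was higher and 7 lower when adjusted over the list alone. That camera call (adjusted p = 0.000641, adjusted p = 0.41 with an estimated correlation) was lost without Tfh_OTII replicate 1 (adjusted p = 0.0788). The fall was not particular to that list. Of 23 Th1 programme genes limma called 0, with 5 lower when adjusted over the list alone (camera adjusted p = 0.00137, adjusted p = 0.624 with an estimated correlation). Of 20 checkpoint and exhaustion genes, 3 were lower, and 1 was higher and 6 lower when adjusted over the list alone (camera adjusted p = 0.000361, adjusted p = 0.435 with an estimated correlation). Of 16 B cell markers, 2 were lower, 1 without each Tfh_WT library and Tfh_OTII replicate 3, and 2 when adjusted over the list alone (camera adjusted p = 0.000594, adjusted p = 0.41 with an estimated correlation). Of 12 CD8 T and NK cell markers, 2 were lower, and 1 without Tfh_WT replicate 2 or 3 or Tfh_OTII replicate 1 or 3, and 1 was higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.00866, adjusted p = 0.43 with an estimated correlation). This camera call was lost with the filter at 5 TPM combined with scaling (adjusted p = 0.0919).

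The comparison of Tfh_tumour with Th1_WT sets the tumour cells against the IL-12 culture. Foxp3 rose from 0.9 ± 0.544 TPM in Th1_WT to 91.7 ± 48.6 in Tfh_tumour (SD, n = 3 each), by 5.52 ± 0.39 log2 as deposited (SE; adjusted p = 4.16e-06) and 4.74 ± 0.34 after scaling. Ikzf2 (Helios), a regulatory T cell transcription factor, rose from 3.75 ± 1.89 to 197 ± 105 TPM, and Lrrc32 (GARP), which tethers latent TGFβ, from 0.456 ± 0.0567 to 30 ± 8.44 TPM. The transcription factor Maf, its target Il10 and the effector regulator Prdm1 (Blimp-1) rose by 4.13, 3.78 and 3.07 log2 after scaling. Of follicular genes, Bcl6 rose by 2.49 ± 0.23 log2 as deposited (adjusted p = 2.02e-05) and 1.56 ± 0.21 after scaling (adjusted p = 0.000867), Tox2, which helps to set up Bcl6 expression, by 1.83 after scaling, and Cxcr5 by 2.44 ± 0.29 as deposited and 1.53 ± 0.30 after scaling (adjusted p = 0.00514). Of all 27 Tfh programme genes, 21 were higher and 1 lower as deposited, also when adjusted over the list alone, and 12 were higher, 4 lower and 11 not called after scaling. Their camera call (adjusted p = 0.00423, adjusted p = 0.629 with an estimated correlation) was lost with the filter at 5 TPM (adjusted p = 0.244; range over alternatives with the preset correlation 5.51e-05 to 0.244). The Cxcr5 call was lost when the fit held only these groups and was scaled (adjusted p = 0.0544; range over alternatives 4.38e-05 to 0.0544). Tumour cells were sorted as CXCR5+ PD1+, so a higher Cxcr5 level may come from the sort. Ctla4 and Tigit rose by 2.68 and 2.83 log2 after scaling, the chemokine Ccl5 by 2.51 and Penk by 3.79. Ifit3 rose from 1.05 ± 0.241 to 269 ± 303 TPM, the RNA sensor Ifih1 by 3.14 log2 after scaling, Rtp4 by 4.21 and Gbp9 by 2.40. Lyz2, the integrin Itgam of myeloid cells and Spp1 (osteopontin) rose by 5.28, 3.07 and 5.66 log2 after scaling. Egr1, an immediate early gene, rose by 1.87, and the division genes Ccnb2 and Ube2c by 1.82 and 1.35 after scaling.

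Lower in Tfh_tumour than in Th1_WT were Lipe (-3.86 log2 after scaling), Smarcad1 (-3.74) and the splicing gene Zrsr1, which fell from 466 ± 280 to 84.6 ± 15.5 TPM. The cytotoxic protease gene Gzma fell from 9.12 ± 6.07 to 1.25 ± 0.812 TPM (-2.0 ± 0.46 log2 as deposited, adjusted p = 0.00339, and -2.95 ± 0.48 after scaling). Ccr7, the lymph node homing receptor, fell from 153 ± 39.4 to 75.4 ± 17.4 TPM, and the naive or memory genes Dapl1 and Id3 had log2 fold changes of -2.90 and -2.66 after scaling. Of all 17 naive and central memory genes, 11 were higher and 2 lower as deposited (4 lower without Th1_WT replicate 1), 11 and 4 when adjusted over the list alone, and 5 were higher and 6 lower after scaling. Camera pointed down without a call (adjusted p = 0.638). The list's median was 1.32 as deposited and 0.13 after scaling, and its mean 0.98 and -0.16. Ifng had 46.1 ± 25.9 TPM in Tfh_tumour and 135 ± 72 in Th1_WT (-1.56 ± 0.50 as deposited, adjusted p = 0.0212, and -2.75 ± 0.54 after scaling, adjusted p = 0.00475; range over alternatives 0.0035 to 0.0939). The Ifng call was lost in a fit of only these groups (0.0675) and without Tfh_tumour replicate 2 (0.0939), Th1_WT replicate 2 (0.0935) and Th1_WT replicate 3 (0.0611). Pdcd1 (1.96 ± 0.37 as deposited, 0.85 ± 0.35 after scaling, adjusted p = 0.105; range over alternatives 8.28e-05 to 0.228) and Cd8a (1.15 ± 0.29 and 0.25 ± 0.27, adjusted p = 0.562; range over alternatives 0.0049 to 0.658) were called only as deposited. Il21 was not called (6.89 ± 2.09 against 5.02 ± 3.19 TPM, adjusted p = 0.235 as deposited and 0.481 after scaling). Tbx21 (0.40 as deposited, adjusted p = 0.331, and -0.74 after scaling, adjusted p = 0.1; range over alternatives 0.0358 to 0.741) and Cd4 (0.54, adjusted p = 0.265, and -0.66 after scaling, adjusted p = 0.2; range over alternatives 0.000335 to 0.694) were not called, and without Th1_WT replicate 3 they were (log2 fold changes 0.80 and 1.17, adjusted p = 0.0358 and 0.000335).

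Here limma called 11501 genes higher and 140 lower as deposited (98.8% higher) and 2434 higher and 1764 lower after scaling (58% higher); 2434 higher and 128 lower genes were called both ways, and 10 in opposite directions. The scaled count of 4198 fell to 2616 without Tfh_tumour replicate 2. Without Th1_WT replicate 1 the balance turned to 2084 higher and 2107 lower. All 21 Treg programme genes were higher as deposited, also when adjusted over the list alone, and 16 after scaling (camera adjusted p = 1.4e-10, adjusted p = 0.629 with an estimated correlation). Of 32 type I interferon response genes, 31 were higher, also when adjusted over the list alone, and 30 after scaling (camera adjusted p = 5.67e-11, adjusted p = 0.629 with an estimated correlation). Of 25 macrophage and monocyte markers, 24 were higher, 25 when adjusted over the list alone and 18 after scaling (camera adjusted p = 3.52e-05, adjusted p = 0.717 with an estimated correlation). Of 40 cell cycle genes, 29 were higher as deposited, 30 when adjusted over the list alone and 14 after scaling (camera adjusted p = 0.000255, adjusted p = 0.736 with an estimated correlation). After scaling 8 were higher without Tfh_tumour replicate 2, and 9 higher and 11 lower without Th1_WT replicate 1; the camera call was lost with the filter at 5 TPM (adjusted p = 0.0529, the highest over alternatives with the preset correlation, with 1.83e-07 the lowest). Of 31 immediate early and dissociation stress genes, 25 were higher as deposited and 28 when adjusted over the list alone (camera adjusted p = 0.00423, adjusted p = 0.856 with an estimated correlation). After scaling 5 were higher and 1 lower, with 14 higher without Tfh_tumour replicate 1 and 3 without Tfh_tumour replicate 3 or Th1_WT replicate 1. None was lower without replicate 1 or 3 of either group. That camera call was lost with the filter at 5 TPM (adjusted p = 0.244; range over alternatives with the preset correlation 9.55e-07 to 0.244). Ribosomal protein genes were called by camera in the downward direction (adjusted p = 1.53e-14, adjusted p = 0.629 with an estimated correlation), although as deposited 1 of 30 was higher and 1 lower, and 1 higher when adjusted over the list alone. Without Tfh_tumour replicate 2 or 3 the lower count was 0 and without Th1_WT replicates 1, 2 and 3 it was 7, 2 and 2, with 3 higher without the last. After scaling 25 of them were lower and 28 when adjusted over the list alone, with 14 and 15 lower without Tfh_tumour replicates 2 and 3. Of 21 cytotoxic genes, 10 were higher, 1 lower and 10 not called as deposited, 11 and 1 when adjusted over the list alone, and 2 were higher and 2 lower after scaling. Without Tfh_tumour replicate 2 those were 1 and 4, and without Tfh_tumour replicate 3 they were 1 and 1; 1 was lower without Tfh_tumour replicate 1 or Th1_WT replicate 2, and 1 higher without Th1_WT replicate 3. Cytotoxic medians were 1.07 and 0.16 while camera pointed down (adjusted p = 0.638). Of 21 amino acid and ATF4 response genes, 6 were higher and 1 lower as deposited (10 higher without Th1_WT replicate 3, 0 lower without Tfh_tumour replicate 2 or Th1_WT replicate 2), and 5 and 1 when adjusted over the list alone. After scaling 2 were higher and 9 lower, with 3 lower without Tfh_tumour replicate 2 or Th1_WT replicate 3. The list had medians of 0.30 and -0.90 and a downward camera call (adjusted p = 0.00358, adjusted p = 0.717 with an estimated correlation) that was lost without Tfh_tumour replicate 2 (0.0643) and Th1_WT replicate 3 (0.315).

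The comparison of Tfh_tumour with Tfh_OTII sets the tumour cells against the culture of receptor-transgenic cells. Foxp3 rose from 1.97 ± 0.273 TPM in Tfh_OTII to 91.7 ± 48.6 in Tfh_tumour (SD, n = 3 each), by 4.84 ± 0.39 log2 (SE; adjusted p = 2.02e-05). Ikzf2 and Maf rose by 4.08 and 4.35 log2, and the costimulatory receptor Icos, needed for Tfh cells and expressed on regulatory cells, rose from 24 ± 3.06 to 225 ± 137 TPM. Bcl6 rose from 4.4 ± 0.14 to 14.5 ± 3.97 TPM (1.5 ± 0.23 log2, adjusted p = 0.00117), Cxcr5 from 5.1 ± 1.26 to 14 ± 2.72 TPM (1.30 ± 0.29, adjusted p = 0.00859) and Tox2 by 1.71 log2. The sort of tumour cells on CXCR5 bears on the Cxcr5 difference. Il21 fell from 69.8 ± 2.66 to 6.89 ± 2.09 TPM (-3.20 ± 0.38, adjusted p = 0.000187). The chromatin organiser Satb1 fell from 630 ± 15 to 120 ± 27.8 TPM, and Lef1 and Id3 had log2 fold changes of -1.20 and -1.63. Prdm1 rose by 3.46 log2, Il10 by 4.78, the inhibitory receptor Havcr2 (TIM3) by 3.41 and Nt5e by 3.52, while Cd274 (PD-L1) rose from 31.5 ± 1.19 to 179 ± 58.8 TPM. Tbx21 rose from 4.63 ± 0.782 to 19.8 ± 5.71 TPM (1.86 ± 0.35, adjusted p = 0.00343). Birc5 fell from 135 ± 17.6 to 17.4 ± 4 TPM (-2.89 ± 0.24, adjusted p = 2.36e-05), and Ccnb1 and Tpx2 had log2 fold changes of -2.46 and -2.79. Slc2a3, the glycolytic kinase Pgk1, Fam162a and the sterol pathway gene Fdps had log2 fold changes of -2.06, -1.71, -2.0 and -1.5. Of interferon-induced genes, Ifit3 rose by 5.85, Rtp4 by 5.17, Oasl2 by 4.43, Irgm1 by 3.11 and Cxcl10 by 5.53 log2. Of myeloid and antigen presentation genes, the Fc receptor chain Fcer1g rose from 0.989 ± 0.0627 to 105 ± 121 TPM, the myeloid regulator Spi1 by 3.29 log2, the class II gene H2-Aa by 4.07 and the invariant chain Cd74 from 18.7 ± 1.58 to 218 ± 159 TPM. The B cell genes Cd22 and Igkc rose by 2.03 ± 0.34 and 2.02 ± 0.26 log2. Trac fell from 2010 ± 79.9 to 592 ± 227 TPM, and Eif2s3y and Ddx3y had log2 fold changes of -5.32 and -3.64. Pdcd1 was not called (1.11 ± 0.37, adjusted p = 0.059; range over alternatives 0.0136 to 0.172), nor were Ifng (adjusted p = 0.874), Cd4 (adjusted p = 0.904) and Cd8a (adjusted p = 0.329).

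Here 1858 genes were higher and 1698 lower by limma, 3556 together, and 2246 and 2011 without Tfh_OTII replicates 2 and 3. The balance turned to 1635 higher and 1938 lower after scaling and to 1512 and 2086 in a fit of only these groups. It was 2540 and 659 on named protein-coding genes alone. More genes were lower than higher also without Tfh_tumour replicate 2 (1280 and 1451) and Tfh_OTII replicate 3 (910 and 1101). Of 27 Tfh programme genes, 12 were higher and 6 lower (3 lower without Tfh_OTII replicate 3), and 13 and 6 when adjusted over the list alone. Their camera call (adjusted p = 0.0193, adjusted p = 0.407 with an estimated correlation) was lost without Tfh_tumour replicate 1 (0.107) and Tfh_OTII replicate 1 (0.168). Of 17 naive and central memory genes, 1 was higher (2 without Tfh_tumour replicate 1) and 3 lower, 2 and 5 when adjusted over the list alone, and camera did not call them (adjusted p = 0.269). Of 16 B cell markers, 11 were higher and 5 not called, also when adjusted over the list alone (camera adjusted p = 2.3e-07, adjusted p = 0.315 with an estimated correlation); without Tfh_OTII replicate 2 or 3 the count was 7. Of 40 cell cycle genes, 35 were lower and 36 when adjusted over the list alone (camera adjusted p = 2.79e-30, adjusted p = 0.315 with an estimated correlation). Of 24 cholesterol synthesis genes, 6 were lower, also when adjusted over the list alone (camera adjusted p = 3.8e-06, adjusted p = 0.315 with an estimated correlation). Of 32 type I interferon response genes, 30 were higher and 32 when adjusted over the list alone, with a median of 2.90 (camera adjusted p = 7.88e-23, adjusted p = 0.315 with an estimated correlation). Of 25 macrophage and monocyte markers, 17 were higher and 22 when adjusted over the list alone, with a median of 2.3 (camera adjusted p = 7.03e-13, adjusted p = 0.315 with an estimated correlation). Of 16 dendritic cell and antigen presentation markers, 8 were higher and 9 when adjusted over the list alone (camera adjusted p = 3.01e-06, adjusted p = 0.315 with an estimated correlation). Of 21 Treg programme genes, 14 were higher and 16 when adjusted over the list alone (camera adjusted p = 1.14e-10, adjusted p = 0.315 with an estimated correlation). Of 23 Th1 programme genes, 9 were higher and 1 lower, and 13 and 2 when adjusted over the list alone (camera adjusted p = 0.00081, adjusted p = 0.407 with an estimated correlation). Without Tfh_tumour replicate 2 the lower count was 2, and it was 0 without each of the other 5 libraries.

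The last question was where the tumour and OT-II cells lie between the wild-type cultures. Of the 9688 genes called between Tfh_WT and Th1_WT as deposited, 90.3% lay on the Tfh_WT side of the midpoint in Tfh_tumour, against 84.9% of all genes above the midpoint. After scaling the share was 78.5% of 3352 genes, against 55.1% of all genes. For Tfh_OTII the shares were 88.7% as deposited and 82.7% after scaling, where 79% and 52.6% of all genes lay above the midpoint. Its scaled share was 75.8% of the higher and 94.4% of the lower genes. Genes higher in Tfh_WT moved up in Tfh_tumour (limma camera adjusted p = 1.06e-11) and those lower moved down (adjusted p = 1.67e-40), and in Tfh_OTII the adjusted p-values were 5.4e-24 and 2.1e-56. After scaling they were 1.53e-09 and 3.76e-37 in Tfh_tumour and 1.27e-23 and 8.04e-44 in Tfh_OTII. With an estimated correlation the higher genes of Tfh_tumour were no longer called (adjusted p = 0.071), and the other values were 0.00248 for its lower genes and 0.0195 and 0.00163 in Tfh_OTII. On an axis scaled so that the mean of Th1_WT is 0 and that of Tfh_WT is 1, Tfh_tumour libraries scored from 0.73 to 0.78 and Tfh_OTII libraries from 1.06 to 1.12. The genes of that axis were chosen on Tfh_WT and Th1_WT, whose own libraries scored from 0.96 to 1.03 and from -0.04 to 0.05. Th1_WT also stood apart in library composition, with 32.2% of symbols at 0 and 46.5% of TPM in satellite-like models. The share of symbols at 0 was 16.3% in Tfh_tumour, 10.2% in Tfh_WT and 17.2% in Tfh_OTII. Scaling does not restore genes listed at 0, so a position away from Th1_WT may reflect composition as well as cell state. These were not told apart.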

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

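Trimmed-mean scaling, scaling on genes at 10 TPM or more, scaling with the replicate block, the filter at 5 TPM and scaling combined with that filter, with a fit of only the groups compared or with a 2-fold limit on axis genes, and, for positions, an estimated correlation and a fit of 3 groups were chosen after the data were seen. The alternatives written for counts (other count tests, count filters and count-based size factors) were not run, because the files hold TPM. Depth is unknown, so what it limits cannot be stated. Shares of the position results ranged over their alternatives from 77.9% to 92.3% for Tfh_tumour and from 80.5% to 97% for Tfh_OTII. Genes higher in Tfh_WT kept their direction and their camera call under these alternatives, except that with an estimated correlation Tfh_tumour, at 90.3%, was no longer past the threshold (adjusted p = 0.071; the cause was not tested). Genes lower in Tfh_WT did so too, but were not tested among the 200 genes with the smallest p, of which 1 was lower. Genes called in Tfh_WT against Th1_WT numbered 9688 as deposited, 3352 with median-of-ratios scaling, 3335 with trimmed-mean scaling, 3674 with scaling on genes at 10 TPM or more, 3512 with scaling and the 5 TPM filter, 2565 with scaling and a fit of only these groups, 2247 on named protein-coding genes alone, and from 6336 to 10380 with 1 library left out. In Tfh_tumour against Th1_WT the 11641 became 4198, 4179, 4565, 4388, 1341 and 4261 under the same settings. Scaling removes the share taken by the satellite-like models by construction. Adding that share to simulated libraries moved the median log2 of unchanged genes by 0.69. In Tfh_WT against Th1_WT scaling moved the tested genes by 0.742. Each simulated Th1_WT library got the same mean share, whereas the real shares ranged from 33.7% to 62.3%. The other simulated libraries held a level averaged over all groups. The nearness of the values thus does not show how much of the real shift came from these models. Other causes were not tested. In Tfh_tumour against Tfh_WT the 489 genes became 262 with a pseudocount of 0.1, 833 on named protein-coding genes, 753 with scaling on genes at 10 TPM or more, 951 with scaling and the 5 TPM filter, and 94 to 882 with 1 library left out. In Tfh_OTII against Tfh_WT the 555 became 359 with a pseudocount of 0.1, 278 on named protein-coding genes, 2857 in a fit of only these groups, 1223 in that fit with scaling, and 144 to 457 with 1 library left out. In Tfh_tumour against Tfh_OTII leaving out 1 library gave 2011 to 3411. For these counts the cause was not tested.

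With a correlation estimated for each list, 0 lists were called by camera in each comparison, against 14, 17, 15, 17 and 20 of 32 in the order of the report; at an unadjusted p under 0.05 there were 2, 7, 3, 1 and 4. fry called 24 in Tfh_WT against Th1_WT, 9 in Tfh_tumour against Tfh_WT, 3 in Tfh_OTII against Tfh_WT, 27 in Tfh_tumour against Th1_WT and 18 in Tfh_tumour against Tfh_OTII; it does not compare a list with other genes. The filter at 5 TPM ended 6, 2, 0, 9 and 1 camera calls in the order of the report. In Tfh_WT against Th1_WT these were the Tfh programme, STAT3, Th17, Th2, checkpoint and glycolysis lists (adjusted p from 0.0904 to 0.345). In Tfh_tumour against Tfh_WT they were the Th1 programme and immediate early lists (0.127 and 0.0958). In Tfh_tumour against Th1_WT they were the Tfh programme, STAT3, Th17, tissue residency, interferon gamma, cell cycle, unfolded protein response, immediate early, and CD8 T and NK cell lists (0.0529 to 0.38). In Tfh_tumour against Tfh_OTII it was the sex-linked list (0.0509). Each of the other scaling, filter, pseudocount, block and gene choices ended at most 4 calls in a comparison, among them the Tfh programme and glycolysis calls with trimmed-mean scaling in Tfh_WT against Th1_WT (both 0.0504). The cause was not tested.

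The replicate number as a block gave 279 genes in Tfh_tumour against Tfh_WT, and with scaling 2793 in Tfh_WT against Th1_WT, 369 in Tfh_OTII against Tfh_WT and 3507 in Tfh_tumour against Th1_WT; a block uses up degrees of freedom. It ended the calls of Bcl6 (adjusted p = 0.0755; range over alternatives 0.0124 to 0.176) and Foxp3 in Tfh_tumour against Tfh_WT. Correlations of deviations from group means, between libraries of different groups, ranged from -0.386 to 0.303 for the same number (mean -0.054) and from -0.277 to 0.358 for different numbers (mean 0.027). Between Tfh_OTII and Th1_WT the same number gave 0.18, 0.007 and 0.303.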

Other observations

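The tests of same-strand small RNA genes, of genomic DNA, of the interferon ratio between tumour libraries and of other splits of the samples were chosen after the results were seen; the tests of small RNA genes, transcript length, shared reads and a second myeloid list were written before.

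Over all genes tested, 11 of 25 macrophage markers and 24 of 32 type I interferon response genes were higher in Tfh_tumour than in Tfh_WT, and 2 and 8 without Tfh_WT replicate 1 or 2. Neither list was called with an estimated correlation (adjusted p = 0.209 for both). Of a second list of 30 myeloid genes, 100% were higher in Tfh_tumour than in Tfh_WT when adjusted over the list alone and 12 over all genes. In tumour replicates 1, 2 and 3, Psap of that list had 49.2, 377 and 114 TPM (41.8 in Tfh_WT). Its members Ctsb had 36.4, 271 and 79.3 TPM (35.1), Ifitm3 16.7, 352 and 73.5 (8.68) and Thbs1 3.92, 491 and 103 (1.65). Of the macrophage markers, Ctss had 118, 768 and 187 TPM (47.3) and Ccr2 14, 332 and 68.1 (10.2). Cultured Tfh_WT cells had a mean of at least 5 TPM for 11 of the 30 genes. In replicate 1 Psap and Ctsb thus stayed near their Tfh_WT level. So did Ccl6 (1.94 TPM against 2.08 to 3.18 in Tfh_WT libraries) and Lilrb4a (29.6 against 28.5 to 32.4). Others lay above it in replicate 1, such as Mpeg1 (11.4 against 0.64 to 0.954) and Clec4e (23.1 against 1.72 to 2.41). The second list was tested against Tfh_WT only. Some members were higher in Tfh_OTII libraries than in tumour replicate 1, such as Lilrb4a (76.7 to 107 TPM), Ifitm3 (20.6 to 25.2) and Ccl9 (10.9 to 13.5 against 6.71). Others were not, such as Mpeg1 and Clec4e, with at most 1.07 and 1.43 TPM in Tfh_OTII. Among the genes named here, values were highest in replicate 2. Counts without single libraries were not made for this second list. RNA of macrophages or monocytes in cells sorted as CD4+ CXCR5+ PD1+ is a candidate source. A gate on CD11b-negative, CD3-positive single cells could reduce it, which was not tested. Over the 24 interferon genes called, the median log2 ratio of replicate 2 to the mean of replicates 1 and 3 was 2.15, within the interquartile range of the macrophage markers (1.57 to 2.70). The same RNA may carry part of the interferon signal, but no set of T cell genes was compared. Foxp3 (146.6 TPM against 54.1 and 74.4) and Trac (854 against 449 and 473) were also highest in replicate 2. An interferon response of T cells strongest in replicate 2 would give such a ratio too, so the ratio cannot tell these sources apart. An interferon response of the T cells themselves and differences of tumour, sort and culture stay open as untested biological explanations.

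The 9 genes abundant in Tfh_WT and far lower in Th1_WT (Tmem38b, Ctrc, Ttyh1, Eny2, Gm10181, Zfp101, Hist1h2af, Hist1h2ag and Rnf225) were picked at 100 TPM or more and a scaled log2 fold change of at least 4. Of them 55.6% (5 genes) had a small RNA gene overlapping an exon, against a mean of 23.9% in 10000 lists matched for abundance (one-sided permutation p = 0.0347). In Hist1h2af and Hist1h2ag the small RNA lies on the opposite strand, whose reads a stranded library would not give to the host gene. On the same strand the share was 33.3% (Tmem38b, Eny2 and Rnf225), against a mean of 23.3% (one-sided permutation p = 0.351). Whether kallisto used the strand is not stated, so reads of small RNA counted to the host gene could neither be shown nor excluded. Short transcripts stay open too: the median longest transcript was 2862 bases, within the 95% range of 684 to 3973 in matched lists (one-sided permutation p = 0.905). The rule written before counted a median at or above the mean of matched lists, 1843 bases, against short transcripts. By that rule the median went against them, but the wider 95% range was used here. Culture conditions stay open as an untested biological explanation.

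The satellite-like models took up to 62.3% of TPM in Th1_WT libraries. Whether reads shared between near-identical models set how they are divided stays open: the lowest Spearman correlation between libraries over the 12 models was 0.867, but over all genes tested it ranged from 0.793 to 0.954. Genomic DNA in the libraries would raise silent genes too. The scaled median of 1405 olfactory receptor genes in Th1_WT was 0.831 times that in Tfh_WT, with library ranges that overlap, but the rise that DNA would need depends on the unknown satellite content of the reads, so DNA and transcription of the repeats cannot be told apart. The culture with IL-12 is an untested biological explanation.

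The 6 libraries of a comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 9688 genes in Tfh_WT against Th1_WT (highest other 1), 489 in Tfh_tumour against Tfh_WT (4), 555 in Tfh_OTII against Tfh_WT (2), 11641 in Tfh_tumour against Th1_WT (5) and 3556 in Tfh_tumour against Tfh_OTII (2); in each, 1 of the 10 splits gave as many.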
